A study of Mus musculus with 12 samples.

How the data were processed

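Polyadenylated RNA was sequenced from hippocampi of adult C57BL/6 mice, wild type (WT) or lacking NONO (knockout, KO), as stranded mRNA libraries on an Illumina instrument, per the labels' protocols. The 12 libraries fall into 4 groups of 3 by genotype and by the labels CT10 and CT22, which the labels do not spell out. Groups and replicate numbers were taken from the sample titles. Nothing in the labels says that the libraries of a group came from separate animals, so p-values measure only the spread between these samples, which may be technical. The protocol names both paired-end and single-end reads without assigning either to a library.

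Per the submitters' processing notes, FastQC, TopHat 1.3.3, RSEM 1.2.5 and edgeR 3.0.6 were used with the mouse build mm10. The deposited file of each library holds estimated counts, which need not be whole, for 30383 transcripts, per the file headers. The authors' deposited table of the series compares KO with WT. It gives a log2 ratio, a p-value and an adjusted p-value per gene, per the file headers, and 12 deposited columns of normalised signal. Each signal column was that library's summed count times a single factor, between 0.761 and 1.827 by library: for 99.27% to 99.42% of the genes of at least 50 counts the ratio lay within 1% of the factor. All 12 of these columns matched a sample title, and 0 columns were left unmatched.

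The estimated counts were summed per gene symbol to 23329 genes and rounded to whole numbers. Library totals ran from 4435606 counts in KO CT22 replicate 2 to 10911046 counts in WT CT22 replicate 3, so the values of that KO library carry the largest counting error. A gene with 0 counts in a library is given a floor of 3 counts. Exact Poisson intervals at 95% and these floors cover counting error only, since the reads carried no molecular identifiers. Reads of near-identical gene copies were divided between them by estimation, so single members of such families are uncertain. Whether the counting used the strand is not given in the sources used here, so overlapping and antisense genes are uncertain as well.

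Genes were tested in R 4.3.3 with edgeR 4.0.16. Low counts were removed by filterByExpr by group (minimum count 10), which left 14131 genes. Libraries were scaled by TMM, with factors from 0.979 to 1.021. A robust quasi-likelihood model with 4 group means was fitted to all 12 libraries, with 8 residual degrees of freedom, a common dispersion of 0.0151 and a biological coefficient of variation of 12.3%. The contrasts were KO against WT averaged over both CT labels, KO against WT at CT10 and at CT22, the difference between these effects, and CT22 against CT10 in WT and in KO. Benjamini-Hochberg adjustment ran over all genes tested, with a threshold of 0.05. Levels are CPM, the counts of a gene scaled to a common library total by TMM, as mean ± SD, and changes are log2 values with their standard error (SE).

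A set of 34 gene lists, covering complexes, pathways and cell type markers, was fixed before the data were examined. Lists were tested with camera in limma 3.58.1, which compares the genes of a list with all other genes, at a preset correlation of 0.01 and with adjustment over the 34 lists. Each test was repeated with a correlation estimated from these libraries, and with ranks. List tests of KO against WT within each CT label were added after the data were seen. The score of a list in a library is the mean log2 CPM of its members minus their mean over the 12 libraries.

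The rule for naming genes was fixed at the same time. After Nono it took, per contrast, the genes with the largest change among those past the threshold, with a mean of at least 2 CPM and with every library of a group beyond those of the other. Uncharacterised symbols were counted but not named, and members of the lists past the threshold could be named. Few genes passed, so most genes in the text stand outside this rule. Members past the threshold over their list alone, genes called by DESeq2 or in the authors' deposited table, 2900052N01Rik and the genes at chromosome 2 were chosen after their values were seen.

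The procedure was tested on simulated data drawn from the real means and library sizes. Each gene was drawn independently of the others, with the dispersion trend of the real fit. Of 100 genes changed 1.5-fold between KO and WT over both CT labels, 72% were recovered, and of 100 changed 2-fold, 92%, with 4 false calls among 168 over 13987 genes. For KO against WT at CT10 the shares were 52% and 82%, with 9 false calls among 143 over 13986 genes. For CT22 against CT10 in WT they were 52% and 84%, with 5 false calls among 141 over 13970 genes. A list of 30 genes shifted 1.2-fold was found in each of these simulations. The simulations held many changed genes, which eases the adjusted threshold, so these shares may be too high for the real data. The simulated lists were random genes without correlation, whereas choroid plexus markers had an estimated correlation of 0.961 over both CT labels. The list result therefore does not carry over to correlated lists.

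The alternatives fixed in advance were RLE size factors, total counts only, 2 other low-count filters, unrounded counts, DESeq2 1.42.0 with default settings on all 18294 genes with counts, stricter thresholds, a replicate block, fits that ignored or added the CT label, fits of only the 6 libraries of a contrast, estimated correlations, rank-based list tests and leaving out each library in turn. Fits without 2 KO libraries whose clock genes lay out of place, without the library of each group with the highest choroid plexus score, and with that score as a covariate were chosen after the data were seen, as was the repeat of the glucocorticoid list test at CT10 in each run with an estimated correlation and that of DESeq2 on the genes edgeR tested. Replicate pairs within groups differed by more than sampling noise (chi-square per degree of freedom 2.92 to 20.26), so no library was counted as a duplicate. Coordinates are on mm10, as the files give them. Isoform levels were not analysed here.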

Results

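The series profiled hippocampal polyadenylated RNA of WT mice and of mice lacking NONO, a nuclear RNA- and DNA-binding protein of the DBHS family found in paraspeckles. Each genotype was sampled under the labels CT10 and CT22 with 3 libraries per group, 12 in all. Library totals ran from 4435606 counts in KO CT22 replicate 2 to 10911046 counts in WT CT22 replicate 3. The Y-linked gene Ddx3y was read at 38.6 to 53.7 CPM in the 12 libraries and Xist at no more than 0.24 CPM.

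The targeted gene was examined first. Nono (chromosome X, 101429651 to 101448593, plus strand) stood at 163 ± 7.38 CPM in WT and at 0.29 ± 0.244 CPM in KO (SD, n = 6 each). The KO libraries held 0, 1 and 2 counts at CT10 and 2, 3 and 4 counts at CT22, against 1147 to 1814 counts in each WT library. Their total of 12 counts (95% exact Poisson interval 6.2 to 21) was 0.157% of the WT level, with a counting interval of 0.0812% to 0.274%. KO CT10 replicate 1, with 0 counts, allows up to 0.34 CPM. Nono fell in edgeR's quasi-likelihood test (log2 change −9.41, SE 0.15, adjusted p = 2.22e-15). An exact two-sided permutation test of the CPM values gave p = 0.00216 over 924 splits. No library's Nono count went against its genotype label.

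The first comparison asked which hippocampal genes differ between KO and WT over both CT labels. Sfpq, a DBHS paralog whose product pairs with NONO (chromosome 4, 127021301 to 127037014, plus strand), rose from 147 ± 7.62 CPM in WT to 189 ± 19.9 CPM in KO (SD, n = 6 each; log2 change 0.36, SE 0.05, edgeR adjusted p = 0.0398). The uncharacterised gene 2900052N01Rik (chromosome 9, 46913603 to 46927366, plus strand) fell from 34 ± 3.64 to 22.4 ± 2.46 CPM (log2 change −0.60, SE 0.09, edgeR adjusted p = 0.0305). For both genes all 6 KO libraries lay beyond the WT libraries of the same CT label. With Nono these were the 3 genes past the threshold of 14131 in edgeR, 1 higher and 2 lower, and 897 genes had an unadjusted p under 0.05 where chance gives 707. The count was 8 without WT CT22 replicate 1, 5 without KO CT10 replicate 2, 2 without WT CT22 replicate 3 and 1 without each of the other 9 libraries. With libraries left out in turn, Sfpq kept its call without KO CT10 replicate 2 or WT CT22 replicate 1, and the gene 2900052N01Rik also without WT CT22 replicate 3. In the other runs their adjusted p values lay from 0.074 to 0.19 and from 0.0652 to 0.189, while the log2 changes over all 12 runs were 0.33 to 0.38 and −0.66 to −0.55. The Sfpq call was also lost in the fits that ignored the CT label (adjusted p = 0.0803) or added it to genotype (0.102), where 2900052N01Rik kept its call (0.0196 and 0.0413). Sfpq and 2900052N01Rik both lost their calls without the 2 KO libraries out of place by clock genes (adjusted p = 0.253 and 0.234), without the library of each group highest in choroid plexus markers (0.448 and 0.225) and with the choroid plexus score as a covariate (0.0818 and 0.0513). Without the 2 KO libraries the log2 changes were 0.33 for Sfpq and −0.60 for 2900052N01Rik.

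**Figure D1:**
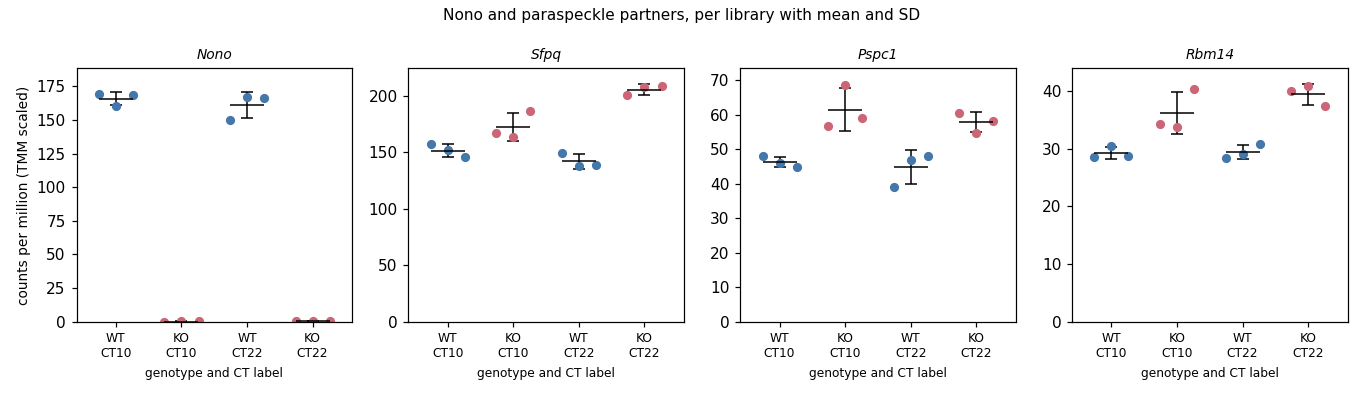
TMM-scaled CPM (vertical axes) of Nono, Sfpq, Pspc1 and Rbm14 in each library (points) by genotype and CT label, with the mean and SD of 3 libraries per group (bars). Sfpq lies between 138 and 157 CPM in the WT libraries and between 164 and 209 CPM in the KO libraries.

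Paraspeckle and DBHS partners, 19 genes of the proteins and RNA found with NONO in the nucleus, stood higher in KO (14 higher and 5 lower, median log2 change 0.04, camera adjusted p = 0.00315). The call was lost with an estimated correlation (adjusted p = 0.502), with ranks (adjusted p = 0.0831) and without KO CT22 replicate 1 (adjusted p = 0.0682). Adjusted over the list alone 3 members passed, against 1 over all genes tested, and these were Sfpq, the DBHS paralog Pspc1 and the paraspeckle protein gene Rbm14. At CT10 taken alone the list did not pass (9 higher and 10 lower, median 0.00, camera adjusted p = 0.151), and Sfpq had a log2 change of 0.19 (edgeR adjusted p = 1). At CT22 the list passed (16 higher and 3 lower, median 0.08, camera adjusted p = 0.00989). That call was lost with an estimated correlation (0.527), with ranks (0.0559) and without WT CT22 replicate 1 (0.102) or KO CT22 replicate 1 (0.208). Pspc1 stood at 45.5 ± 3.36 CPM in WT and 59.5 ± 4.81 CPM in KO (SD, n = 6 each; log2 change 0.39, SE 0.07, edgeR adjusted p = 0.0918 over all genes). Rbm14 stood at 29.3 ± 1.03 and 37.7 ± 3.14 CPM (log2 change 0.36, edgeR adjusted p = 0.101). All 6 KO libraries exceeded the WT libraries of their CT label in each of these genes. Neat1, an RNA of paraspeckles, stood at 88.4 ± 16.4 and 103 ± 21.3 CPM and did not pass (log2 change 0.23, edgeR adjusted p = 0.815). Neat1 was counted over chromosome 19, 5842302 to 5845478, minus strand. Forms that reach beyond this span or lack a poly(A) tail were not measured as such, so the value does not cover all Neat1 RNA.

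Glucocorticoid-responsive genes stood lower in KO, with a negative log2 change in 23 of 26 members (median −0.17, camera adjusted p = 3.73e-08, and adjusted p = 0.465 with an estimated correlation). Adjusted over the list alone 8 members passed, all lower, against 0 over all genes tested in edgeR. Tsc22d3, which encodes the anti-inflammatory protein GILZ, stood at 83.4 ± 18.5 CPM in WT and 60.1 ± 9.05 CPM in KO (SD, n = 6 each; log2 change −0.45, edgeR adjusted p = 0.176), lower in 6 of 6 KO libraries than the WT libraries of the same CT label. DESeq2 called Tsc22d3 and no other member of these 26 (adjusted p = 0.00886). At CT22 taken alone the list did not pass (15 of 26 lower, median −0.02, camera adjusted p = 0.375), and 0 members passed adjusted over the list alone.

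Astrocyte markers also stood lower (15 of 20 members, median log2 change −0.11, camera adjusted p = 4.79e-05, and adjusted p = 0.502 with an estimated correlation). Adjusted over the list alone 5 members passed, against 0 over all genes in edgeR: S100b, F3, Mlc1 and Aldoc were lower and Sox9, a glial transcription factor, was higher. S100b, a calcium-binding protein of astrocytes, stood at 123 ± 8.05 CPM in WT and 92.9 ± 10.1 CPM in KO (SD, n = 6 each; log2 change −0.41, edgeR adjusted p = 0.0696), and Sox9 at 26.9 ± 4.98 and 33.5 ± 4.51 CPM (log2 change 0.33, edgeR adjusted p = 0.46). Microglia markers were lower in 17 of 19 members (median −0.10, camera adjusted p = 9.74e-06, and adjusted p = 0.502 with an estimated correlation). Of the GABA-A receptor subunits, Gabra2 (alpha-2) alone passed over the list of 12, at 49.6 ± 3.1 CPM in WT and 39.0 ± 3.71 CPM in KO (log2 change −0.35, edgeR adjusted p = 0.176 over all genes). The GABA-A list itself did not pass (camera adjusted p = 0.213).

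Cytosolic ribosomal protein genes were lower in KO in 79 of 79 members (median log2 change −0.11, camera adjusted p = 1.12e-13), and oxidative phosphorylation genes in 71 of 73 (median −0.09, camera adjusted p = 3.07e-10). With estimated correlations of 0.739 and 0.611 the adjusted p was 0.638 for both, and 0 members of either passed adjusted over the list alone. At CT10 taken alone neither list passed: ribosomal protein genes were lower in 47 of 79 members (median −0.01, camera adjusted p = 0.418), and oxidative phosphorylation genes higher in 45 of 73 (median 0.02, camera adjusted p = 0.999). Cholesterol biosynthesis genes were lower (19 of 24, camera adjusted p = 0.00501) and voltage-gated potassium channels higher (24 of 33, camera adjusted p = 0.04), both with an adjusted p = 0.638 under an estimated correlation. The cholesterol call was lost without WT CT10 replicate 2, WT CT22 replicates 1 and 3 or KO CT22 replicates 1 and 2 (adjusted p up to 0.209). The potassium channel call was lost without WT CT10 replicates 2 and 3, KO CT10 replicate 3, WT CT22 replicate 3 or KO CT22 replicate 1 (adjusted p up to 0.273).

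Markers of tissues next to the hippocampus were unequal between the libraries. Meningeal markers were higher in KO (17 of 18, median log2 change 0.61, camera adjusted p = 2.07e-06), as were neocortex markers (16 of 17, 0.19, 0.000914), thalamus and habenula markers (15 of 16, 0.29, 0.00197) and striatum markers (8 of 12, 0.21, 0.0152). Each had an adjusted p = 0.604 with an estimated correlation, and the thalamus and striatum calls were lost without KO CT22 replicate 3 (adjusted p = 0.0784 and 0.282). Choroid plexus markers were higher in 16 of 16 members (median 1.29, camera adjusted p = 0.01, and adjusted p = 0.692 with an estimated correlation). Their call was lost without WT CT10 replicate 1 (adjusted p = 0.0816), KO CT10 replicate 1 (0.454), WT CT22 replicate 1 (0.14) or KO CT22 replicate 3 (0.601). Ttr, the most abundant of them, ranged from 54.5 to 3454 CPM and was highest in WT CT10 replicate 3, KO CT10 replicate 1, WT CT22 replicate 3 and KO CT22 replicate 3 of their groups.

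**Figure D2:**
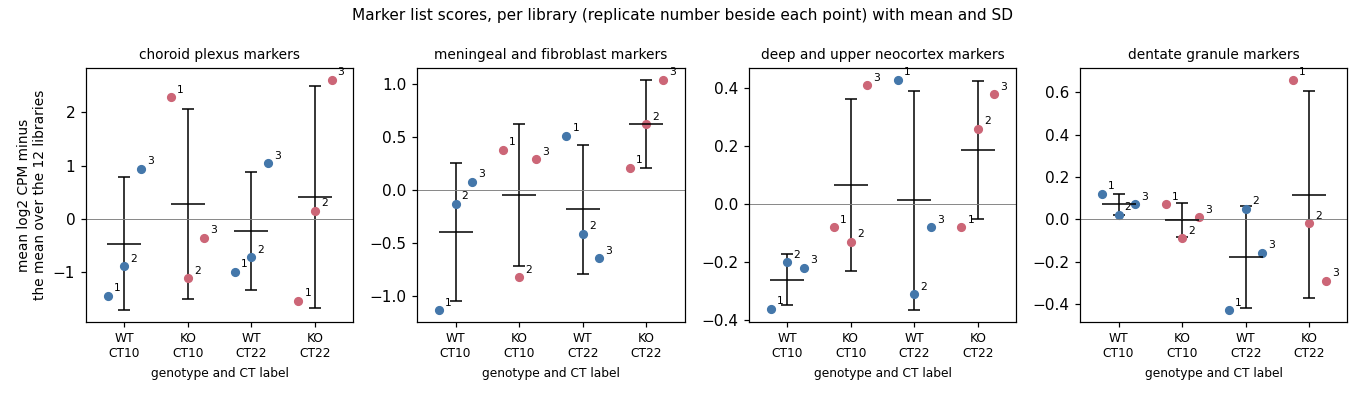
Scores of 4 marker lists (vertical axes, mean log2 CPM of the members minus their mean over the 12 libraries) in each library (points with replicate numbers) by genotype and CT label, with the mean and SD of 3 libraries per group (bars). Choroid plexus scores run from −1.53 to 2.61, and the highest of each group are 0.94, 2.28, 1.04 and 2.61.

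Interferon response genes were higher in 21 of 24 members (camera adjusted p = 0.00315, and adjusted p = 0.638 with an estimated correlation). This call was lost without KO CT10 replicate 1 (adjusted p = 0.467), whose score was 0.75 against at most 0.06 elsewhere. Dentate granule markers were higher (17 of 20, camera adjusted p = 0.0152, and adjusted p = 0.692 with an estimated correlation), but not without WT CT10 replicate 2 (0.0502) or WT CT22 replicate 1 (0.342), and without KO CT22 replicate 1 the direction turned (0.766). Blood genes were higher (5 of 7, camera adjusted p = 0.0152, and adjusted p = 0.604 with an estimated correlation). Their call was lost with ranks (0.0795) and without KO CT10 replicate 1 (0.0535), KO CT10 replicate 2 (0.122) or WT CT22 replicate 1 (0.098). In all, 16 of 34 lists passed at the preset correlation, 10 higher and 6 lower, and 0 with an estimated correlation. The other 18 lists, core clock genes among them, had adjusted p values from 0.0621 to 0.836.

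The authors' deposited table of this comparison holds 28 genes past an adjusted p of 0.05, 11 higher and 17 lower. Of these, 26 were tested here, and 26 had the same direction, 25 an unadjusted p under 0.05 and 3 passed. DESeq2 called 22 genes, 5 higher and 17 lower, of which 19 are past 0.05 in the authors' deposited table and 3 in edgeR. Across 14129 genes the log2 changes here and in the authors' deposited table correlated at r = 0.962, with genes that are not independent replicates. That table, edgeR and DESeq2 all used the same 12 libraries. The shared directions, small p-values and correlation are therefore no independent evidence for these genes. Among the DESeq2 calls, Ndrg2, expressed in astrocytes, stood at 928 ± 77.4 CPM in WT and 736 ± 43.9 CPM in KO (SD, n = 6 each; edgeR adjusted p = 0.0796). Gpc5, a heparan sulfate proteoglycan, stood at 48.9 ± 4.27 and 36.3 ± 3 CPM (edgeR adjusted p = 0.0696), and Upp2, a uridine phosphorylase, at 3.96 ± 0.725 and 1.54 ± 0.578 CPM (0.0828). Bmper, a secreted modulator of BMP signalling, stood at 6.89 ± 0.83 and 11.1 ± 1.17 CPM (edgeR adjusted p = 0.0696). In each of these 4 genes all 6 KO libraries lay beyond the WT libraries of the same CT label. The 4 were picked from genes already called, so this separation adds no separate support. Upp2 rests on few counts: in KO CT22 replicate 2 it was read at 0.448 CPM, below that library's floor of 0.672 CPM.

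The next comparison set KO against WT at CT10. The glucocorticoid-responsive list stood apart, with 21 of 26 members lower in KO (median log2 change −0.24, camera adjusted p = 2.62e-17). Of the 13 lists called here it alone was past the threshold with an estimated correlation (adjusted p = 0.0465, against at least 0.639 for the others). With that correlation the call was lost in 7 of the 12 runs without a library: WT CT10 replicate 2 (adjusted p = 0.13) or 3 (0.16), KO CT10 replicate 1 (0.168) or 2 (0.134), WT CT22 replicate 3 (0.0755), and KO CT22 replicate 1 (0.119) or 2 (0.0656). Blood genes, higher in KO, passed with that correlation without KO CT10 replicate 3 (adjusted p = 0.0194, against 0.0437 for the glucocorticoid list) and without the 2 KO libraries out of place by clock genes (0.0489, where the glucocorticoid list had 0.166). Adjusted over the list alone 9 members passed, all lower, against 0 over all genes tested in edgeR. Sgk1, a kinase gene induced through the glucocorticoid receptor, stood at 108 ± 9.87 CPM in WT CT10 and 65.2 ± 9.92 CPM in KO CT10 (SD, n = 3 each; log2 change −0.73, edgeR adjusted p = 0.664). Ddit4, an inhibitor of mTOR signalling, stood at 77.1 ± 7.45 and 48.9 ± 2.19 CPM (log2 change −0.66, edgeR adjusted p = 0.664), and Tsc22d3 at 98.0 ± 13.9 and 64.4 ± 10.6 CPM (log2 change −0.61, edgeR adjusted p = 0.664). Nfkbia, an inhibitor of NF-kappaB, stood at 34 ± 2.71 and 21.2 ± 4.55 CPM (log2 change −0.68).

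Over all genes Nono was the 1 gene past the threshold at CT10 in edgeR, and 436 had an unadjusted p under 0.05, fewer than the 707 that chance gives. DESeq2 called 3, all lower, which were Nono, Sgk1 (adjusted p = 0.0189) and Ddit4 (0.0274). In a fit of only the 6 CT10 libraries 4 genes passed, with Sgk1 and Ddit4 among them (edgeR adjusted p = 0.0393 each). Lists called at CT10 numbered 13 at the preset correlation, and 7 without KO CT10 replicate 1.

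Cell type marker lists were also called between KO and WT at CT10, with all libraries at the preset correlation only. Astrocyte markers were lower in 16 of 20 members (camera adjusted p = 0.000818, and adjusted p = 0.639 with an estimated correlation) and interneuron markers higher in 16 of 23 (camera adjusted p = 0.00162, and adjusted p = 0.702 with an estimated correlation), and both kept the call in each run without a library. Neocortex markers were higher in 15 of 17 (camera adjusted p = 0.000199, and adjusted p = 0.702 with an estimated correlation), but not without KO CT10 replicate 3 (0.0863). Endothelial and CA1 markers were higher in 17 of 20 and 11 of 14 (camera adjusted p = 0.00601 and 0.022, and adjusted p = 0.741 for both with an estimated correlation). Without WT CT10 replicate 3 both calls were lost (adjusted p = 0.109 and 0.737), as was the endothelial call without KO CT10 replicate 1 (0.239) and the CA1 call without KO CT10 replicate 3 (0.322). Choroid plexus and blood genes were higher in 16 of 16 and 7 of 7 (camera adjusted p = 0.0256 and 0.00283, and adjusted p = 0.841 and 0.639 with an estimated correlation). Both calls were lost without KO CT10 replicate 1 (0.365, with the direction turned, and 0.117), the choroid plexus call also without WT CT10 replicate 1 (0.403) or 2 (0.176), and the blood call without KO CT10 replicate 2 (0.0781). The remaining calls, interferon response, oligodendrocyte and meningeal genes higher and cholesterol biosynthesis and microglia genes lower, were each lost without KO CT10 replicate 1 (adjusted p = 0.875, 0.323, 0.493, 0.141 and 0.0646), and the interferon direction turned. Without WT CT10 replicate 1 the meningeal (0.923) and microglia (0.208) calls were lost, without WT CT10 replicate 2 the cholesterol (0.441) and microglia (0.0635) calls, and without WT CT10 replicate 3 the oligodendrocyte call (0.557, with the direction turned). Without KO CT10 replicate 2 the oligodendrocyte call was lost (0.17), and without KO CT10 replicate 3 the cholesterol (0.159), microglia (0.388) and meningeal (0.279) calls.

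**Figure D3:**
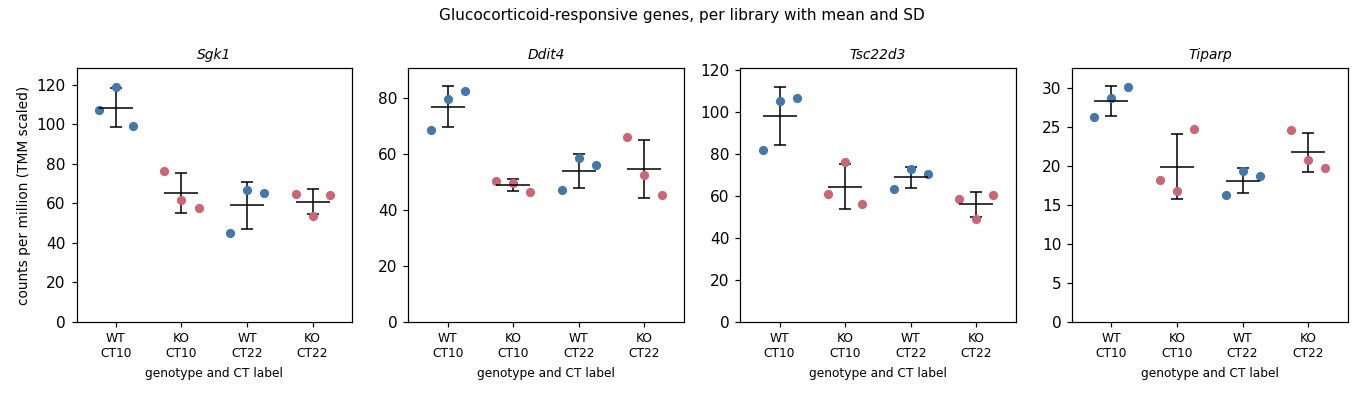
TMM-scaled CPM (vertical axes) of Sgk1, Ddit4, Tsc22d3 and Tiparp in each library (points) by genotype and CT label, with the mean and SD of 3 libraries per group (bars). Sgk1 lies between 98.9 and 119 CPM in WT CT10 and between 45.1 and 76.4 CPM in the other groups.

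At CT22, Sfpq rose from 142 ± 6.56 CPM in WT to 206 ± 4.52 CPM in KO (SD, n = 3 each; log2 change 0.53, SE 0.08, edgeR adjusted p = 0.0349). Sfpq and Nono were the 2 genes past the threshold, and 1543 had an unadjusted p under 0.05 where chance gives 707, while DESeq2 called 31, 20 higher and 11 lower (17 without its independent filtering). The 707 is a mean, and with correlated genes a count can lie far from it without an effect of genotype. A split of the CT22 libraries that mixed the genotypes called 105 genes, as given below. Ribosomal protein genes were lower in 79 of 79 members (median log2 change −0.21, camera adjusted p = 1.69e-19) and oxidative phosphorylation genes in 73 of 73 (median −0.20, camera adjusted p = 5.88e-17), both with an adjusted p = 0.527 under an estimated correlation. CA1 pyramidal markers were lower in 13 of 14 members (median −0.30, camera adjusted p = 9.46e-05, and adjusted p = 0.527 with an estimated correlation). Sgk1 stood at 58.9 ± 12 CPM in WT CT22 and 60.6 ± 6.29 CPM in KO CT22 (log2 change 0.05, edgeR adjusted p = 0.922). The call of Sfpq was kept only without KO CT10 replicate 2, KO CT10 replicate 3 or WT CT22 replicate 1, and was lost without each of the other 9 libraries (adjusted p from 0.0674 to 0.307) and in a fit of only the 6 CT22 libraries (0.527). It was also lost without the 2 KO libraries out of place by clock genes, of which 1 is KO CT22 replicate 1 (adjusted p = 0.123), without the library of each group highest in choroid plexus markers (0.662) and with the choroid plexus score as a covariate (0.0565). The log2 change of Sfpq at CT22 was 0.54 without the 2 KO libraries. The count of genes was 4 without WT CT22 replicate 1, and 1 without each WT CT10 library, KO CT10 replicate 1, WT CT22 replicates 2 and 3 or KO CT22 replicates 1 and 3.

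Marker lists of several cell types and regions were also called at CT22, with all libraries at the preset correlation only. Meningeal markers were higher in KO in 16 of 18 members (median log2 change 0.75, camera adjusted p = 4.15e-05, and adjusted p = 0.573 with an estimated correlation), and dentate granule markers in 19 of 20 (median 0.32, camera adjusted p = 8.79e-05, and adjusted p = 0.607 with an estimated correlation). Thalamus and striatum markers were higher in 14 of 16 and 11 of 12 members (camera adjusted p = 0.00381 each, and adjusted p = 0.573 and 0.527 with an estimated correlation). Oligodendrocyte markers were lower in 18 of 19 (camera adjusted p = 0.00388, and adjusted p = 0.657 with an estimated correlation). Microglia and astrocyte markers were lower in 15 of 19 and 15 of 20 (camera adjusted p = 8.79e-05 and 0.0126, and adjusted p = 0.527 for both with an estimated correlation). The microglia and meningeal calls were kept in each run without a library, and the astrocyte call was lost without WT CT22 replicate 2 (0.194) or KO CT22 replicate 2 (0.121). The dentate call was lost without WT CT22 replicate 1 (adjusted p = 0.0647) or KO CT22 replicate 1 (0.625), the oligodendrocyte call without KO CT22 replicate 1 (0.953), and the thalamus and striatum calls without KO CT22 replicate 3 (0.424 and 0.285). In all, 13 lists passed at CT22 at the preset correlation, 7 higher and 6 lower, and 0 with an estimated correlation. These also held paraspeckle partners. Voltage-gated potassium channels were higher in 25 of 33 (camera adjusted p = 0.00248, and 0.527 with an estimated correlation), a call kept in each run without a library. Metabotropic glutamate receptors and the excitatory postsynapse were higher in 24 of 30 (0.0189 and 0.629 likewise), but not without WT CT22 replicate 3 (0.225), KO CT22 replicate 1 (0.339) or 2 (0.121).

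Whether the effect of the knockout differed between the CT labels was tested directly. For glucocorticoid-responsive genes the effect at CT22 lay above that at CT10 in 19 of 26 members (median difference 0.22, camera adjusted p = 2.74e-05, and adjusted p = 0.609 with an estimated correlation). Adjusted over the list alone 5 members passed, against 0 over all genes tested: Sgk1 (log2 difference 0.78), Tiparp (0.78), Ddit4 (0.68), Errfi1 (0.61) and Klf9 (0.61). No gene passed in edgeR (0, with 861 at an unadjusted p under 0.05 where chance gives 707) or in DESeq2 (0, with 735). Of the lists 12 passed at the preset correlation and 0 with an estimated correlation, where the lowest adjusted p was 0.609. Without KO CT10 replicate 3 the number of lists was 19. This comparison rests on the CT labels of the KO libraries. By clock genes, KO CT10 replicate 3 and KO CT22 replicate 1 lay out of place, as given below. Without these 2 libraries the log2 difference was 0.65 for Sgk1, 0.85 for Tiparp, 0.47 for Ddit4 and 0.72 for Errfi1, and 0 genes passed in edgeR.

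CT22 was then compared with CT10 within WT. Glucocorticoid-responsive genes stood lower at CT22 (18 of 26, median log2 change −0.15, camera adjusted p = 1.11e-06, and adjusted p = 0.562 with an estimated correlation). Adjusted over the list alone 10 members passed, 9 lower and 1 higher, against 0 over all genes in edgeR. Sgk1 had a log2 change of −0.88 (edgeR adjusted p = 0.388, DESeq2 adjusted p = 0.000262), and Plin4, a lipid droplet gene, stood at 2.27 ± 0.259 CPM at CT10 and 6.50 ± 1.96 CPM at CT22 (SD, n = 3 each; log2 change 1.51). The WT CT10 libraries enter this comparison, that of KO with WT at CT10 and that of the effects between labels, so the values of these genes in the 3 comparisons are not independent.

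Of the 24 core clock genes, 2 passed adjusted over the list alone, against 0 over all genes, and the list did not pass (camera adjusted p = 0.286). That list test looks for a shift in a common direction. With 13 members higher and 11 lower it cannot tell whether clock genes differed between the labels. The WT libraries of the 2 labels did not overlap in 11 of the 24 genes, against 16.2% of all genes tested. Gm129, a clock-controlled repressor also called Ciart, stood at 15.0 ± 0.92 CPM at CT10 and 6.83 ± 1.73 CPM at CT22 (SD, n = 3 each; log2 change −1.13), and the period gene Per2 at 59.5 ± 5.90 and 42.2 ± 6.20 CPM (log2 change −0.50). Nr1d1 stood at 110 ± 2.62 and 75.8 ± 6.10 CPM, and Arntl, whose protein drives the loop that Nr1d1 represses, at 27.3 ± 3.75 and 34.9 ± 4.56 CPM. Their edgeR adjusted p values were 0.722 and 0.727.

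CA1 pyramidal markers were higher at CT22 in WT in 13 of 14 members (median log2 change 0.41, camera adjusted p = 3.29e-05, and adjusted p = 0.617 with an estimated correlation), and heat shock genes in 21 of 23 (median 0.11, camera adjusted p = 0.000496, and adjusted p = 0.729 with an estimated correlation). Endothelial and mural markers were higher in 17 of 20 (median 0.21, camera adjusted p = 9.58e-05, and adjusted p = 0.617 with an estimated correlation), a call kept in each run without a library. Neocortex markers were higher in 15 of 17 (camera adjusted p = 0.0068, and adjusted p = 0.729 with an estimated correlation), but not without WT CT22 replicate 1 (0.451). Dentate granule markers were lower in 17 of 20 (camera adjusted p = 0.00292, and adjusted p = 0.729 with an estimated correlation), and CA3 and CA2 markers in 16 of 19 (camera adjusted p = 0.000486, and adjusted p = 0.617 with an estimated correlation). These calls of dentate and CA3 markers were lost without WT CT22 replicate 1 (adjusted p = 0.269 and 0.144), whose scores were −0.43 and −0.55. No gene passed between the labels in WT in edgeR (0, with 955 at an unadjusted p under 0.05 where chance gives 707), and DESeq2 called 4. Lists called numbered 16, and 10 without WT CT22 replicate 1.

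Within KO, clock genes were spread widely inside each CT label. Dbp, an output gene of the clock, was read at 93.7, 106 and 33.6 CPM in KO CT10 replicates 1, 2 and 3 and at 90.9, 32.3 and 32.9 CPM in KO CT22 replicates 1, 2 and 3. Nr1d1 was read at 112, 117 and 72.7 CPM and at 125, 67.0 and 72.4 CPM in the same libraries. The libraries labelled KO CT10 replicate 3 and KO CT22 replicate 1 thus lay near the levels of the other label. Dbp had a log2 change of −0.54 between the labels (edgeR adjusted p = 0.977). No gene passed in KO in edgeR (0, with 447 at an unadjusted p under 0.05, below the 707 that chance gives) or in DESeq2 (0, with 357). Ribosomal protein genes were lower at CT22 in 74 of 79 members (camera adjusted p = 9e-10, and adjusted p = 0.67 with an estimated correlation), but not without KO CT10 replicate 2 (0.999). Of the lists 16 passed at the preset correlation and 0 with an estimated correlation.

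**Figure D4:**
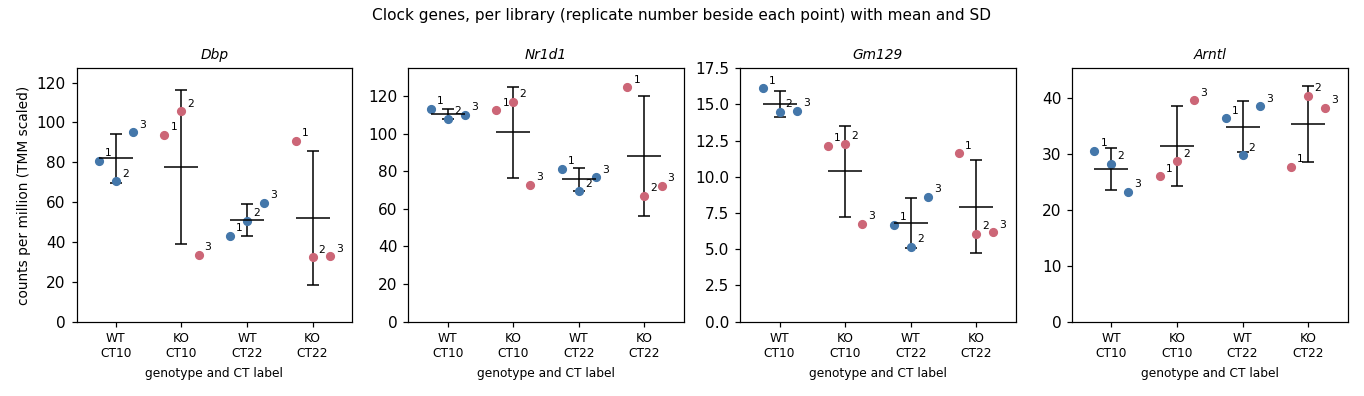
TMM-scaled CPM (vertical axes) of Dbp, Nr1d1, Gm129 and Arntl in each library (points with replicate numbers) by genotype and CT label, with the mean and SD of 3 libraries per group (bars). For Dbp, KO CT10 replicate 3 lies at 33.6 CPM and KO CT22 replicate 1 at 90.9 CPM, near the levels of the other label.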

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

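The fits without 2 KO libraries and with the choroid plexus score, and the list test at CT10 with its runs without a library, were chosen after the result was seen. The tests of other splits of the libraries were planned, except the count without Nono.

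The effect of the knockout differed between CT22 and CT10, by the direct test at the preset correlation, in 12 lists. The median difference in log2 change was 0.20 for metabotropic glutamate receptors and the excitatory postsynapse, 0.17 for voltage-gated potassium channels, 0.22 for glucocorticoid-responsive genes and 0.09 for SR and hnRNP splicing factors. It was 0.42 for dentate granule markers, 0.31 for CA3 and CA2 markers and 0.34 for striatum markers. It was negative for oxidative phosphorylation (−0.20), ribosomal proteins (−0.21), oligodendrocyte markers (−0.38), ependymal markers (−0.41) and CA1 markers (−0.50). Without KO CT22 replicate 1 the calls of splicing factors (adjusted p = 0.0683), oligodendrocyte (0.0683), ependymal (0.969, with the direction turned), dentate (0.166) and CA3 and CA2 markers (0.128) were lost. That library had scores of −0.79 for oligodendrocyte, −1.45 for ependymal and 0.66 for dentate granule markers. The CA3 and CA2 call was also lost without WT CT22 replicate 1 (0.312). The ependymal call was also lost with total counts only (0.0516) and without WT CT10 replicate 1 (0.151), KO CT10 replicate 1 (0.456), WT CT22 replicate 2 (0.138) or WT CT22 replicate 3 (0.0977). The striatum call was lost without WT CT10 replicate 3 (0.114), KO CT10 replicate 1 (0.103), WT CT22 replicate 2 (0.0919) or KO CT22 replicate 3 (0.425). All 12 calls were lost with an estimated correlation (lowest adjusted p = 0.609).

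Other splits of the libraries were fitted in the same way. Each count of splits below includes the real one, and the 100 splits within the CT labels were the real one and a random draw of the others. For KO against WT over both CT labels, 3 of 100 splits within the CT labels gave as many genes as the real 3, and the highest other split gave 93. The real count holds Nono, the deleted gene, which no other split called. Without Nono the real count is 2, and 4 of 100 splits gave as many, with 93 and 53 in the highest others, so these splits are not taken to exclude chance for the other 2 genes. For the difference between labels the real count of genes was 0, which all 100 of 100 splits meet by construction, so this decides nothing, and the highest other gave 53. Chance cannot be excluded for the lists: 38 of 100 splits gave at least the real 16 lists for KO against WT (highest other 23), and 71 of 100 at least the real 12 for the difference (highest other 23). With 10 splits of 6 libraries a share under 0.05 cannot be reached. There the real count and the highest other were 1 and 0 genes for KO against WT at CT10, 2 and 105 at CT22, 0 and 0 for the labels in WT, and 0 and 6 in KO. For lists they were 16 and 14 in WT and 16 and 20 in KO. In WT 1 split gave as many lists, which was the real one, and in KO 4 with the real one among them. The 0 genes of both are met by all 10 splits by construction.

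The split with 105 genes sets WT CT22 replicate 1 and KO CT22 replicates 2 and 3 against the other CT22 libraries, and the split with 93 genes holds the same parting at CT22. Splits that call so many genes point to a structure of the samples. The neocortex scores of these 3 libraries were 0.43, 0.26 and 0.38, against −0.31, −0.08 and −0.08 in the others, and their meningeal scores 0.51, 0.62 and 1.04 against −0.41, −0.64 and 0.21.

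The lower level of glucocorticoid-responsive genes in KO at CT10 was weighed against 2 technical explanations. Its median moved from −0.24 to −0.31 without the 2 KO libraries out of place by clock genes (camera p = 0.00976 with an estimated correlation for this list alone) and to −0.27 with the choroid plexus score as a covariate (camera p = 0.00285 likewise), which argues against either as the whole cause. Adjusted over the 34 lists the call ended in both fits (adjusted p = 0.166 and 0.0968, against 0.0465 with all libraries), with medians no nearer 0 and with fewer libraries or a further coefficient. Without the 2 KO libraries 24 of 26 members were lower, against 21 with all libraries. The members with the clearest changes moved nearer 0 there. The log2 change went from −0.73 to −0.65 for Sgk1, −0.66 to −0.62 for Ddit4 and −0.61 to −0.52 for Tsc22d3. It went from −0.68 to −0.52 for Nfkbia, −0.39 to −0.35 for Klf15 and −0.95 to −0.71 for Hif3a. Of the 12 runs without a library 7 lost the call as well (adjusted p from 0.0656 to 0.168), with medians below 0 in each. An effect of genotype stays open, as do handling and hormone levels at collection, which were not tested.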

How the results depend on the processing

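The fits without 2 KO libraries, without the libraries high in choroid plexus markers and with the choroid plexus score, and the list tests within a CT label, were chosen after the data were seen. Nono kept its direction and call in each alternative run on it, with log2 changes of −9.82 to −9.11 when libraries were left out in turn. RLE factors, total counts, unrounded counts and the filter at 1 CPM in 6 libraries left each count of genes within 1.5 times. For KO against WT over both labels the count was 2 in fits that ignored or added the CT label, 10 with no low-count filter, 22 with DESeq2 and 1 at an adjusted p of 0.01. It was 1 without the 2 KO libraries out of place by clock genes, 1 without the libraries high in choroid plexus markers, 1 with the choroid plexus score as covariate, and 1 to 8 when libraries were left out in turn. At CT10 it was 3 with DESeq2, 4 with only the 6 libraries and 1 to 1 in the runs without a library. At CT22 it was 31 with DESeq2 and 1 to 4 without a library. It was 1 with only the 6 libraries, at an adjusted p of 0.01, without the 2 KO libraries, and without those high in choroid plexus markers. Between the labels in WT it was 4 with DESeq2, 2 with only the 6 libraries, 1 without the 2 KO libraries and 0 to 1 without a library. Without the 2 KO libraries it was 1 in KO, the clock gene Dbp, a call that tests nothing since these libraries were chosen by their clock genes. The difference between labels stayed at 0 in each of these fits. DESeq2 ran on all 18294 genes with counts, and on the 14131 genes edgeR tested it gave the same counts, but 17 at CT22 without its independent filtering. Lists called with an estimated correlation numbered 0, except 1 at CT10, the glucocorticoid list. At CT10 that number was 0 to 2 when libraries were left out in turn, with blood genes as the further list without KO CT10 replicate 3, and blood genes were the 1 list without the 2 KO libraries. Leaving out a library gave 13 to 18 lists over both labels, 7 to 17 at CT10, 12 to 19 at CT22, 11 to 19 for the difference, 10 to 16 in WT and 12 to 18 in KO. With the choroid plexus score there were 10 lists in WT. The cause of these moves was not tested, except that fits with fewer libraries have less to test on.

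With the replicate number as a block, the count of genes was 1 over both labels, 1 at CT10, 1 at CT22 and 0 in the others. Sfpq (adjusted p = 0.108 over both labels and 0.0893 at CT22) and 2900052N01Rik (0.0776) lost their calls, and no count of lists moved by over 1.5 times. The shared numbers did not pair the libraries: 18 pairs of the same number had correlations of −0.237 to 0.328, and 4 of 12 libraries correlated best with their own number.

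Of 1120 values of named genes other than Nono under alternatives, 1039 kept direction and side of the threshold, 43 lost the call, 29 gained it and 9 turned. Most of these values could not lose a call, since the main fit had called only Sfpq and 2900052N01Rik among these genes. All 43 losses are theirs. In the runs without a library Sfpq lost its call in 10 of 12 over both labels and in 9 of 12 at CT22. The call of 2900052N01Rik was lost in 9 of 12. Ttr in KO against WT turned to −0.43 with the choroid plexus score, −0.18 without KO CT10 replicate 1 and −0.12 without KO CT22 replicate 3, and ran from −0.18 to 2.22 when libraries were left out in turn. Sgk1 at CT22, which lies at 0.05, came to −0.12 without WT CT22 replicate 1, −0.01 without KO CT22 replicate 1, and to 0 or just below without KO CT22 replicate 3 and without the 2 KO libraries, in a range of −0.12 to 0.14 without a library. Between the labels in KO, Nr1d1 came to 0.05 and Arntl to −0.04 without the libraries high in choroid plexus markers. None of these values was past the threshold, and the cause was not tested.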

Other observations

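The test of clock phase and that of the chromosome 2 cluster were chosen after the result was seen, and so were the genes at that cluster.

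Members of further lists stood apart by CT label. In WT, Cldn5, a tight junction gene of endothelial cells, had a log2 change of 1.01 at CT22 against CT10 and passed adjusted over its list alone, as did Neto1, an auxiliary subunit of kainate receptors, with −0.51. Ccnd2, a cyclin of dividing progenitors, had −0.32 in WT, and its knockout effect differed between the labels by 0.53. Crhbp, which binds corticotropin-releasing hormone, was higher in KO at CT10 (log2 change 0.60), with a difference between labels of −0.76. Each of these passed adjusted over its list alone and missed the threshold over all genes in edgeR (adjusted p from 0.504 to 1).

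Clock genes placed 2 KO libraries at the other label. On the axis of the WT clock genes (0 for the WT CT10 mean and 1 for the WT CT22 mean) KO CT10 libraries lay at 0.11, 0.13 and 1.19 and KO CT22 libraries at 0.03, 1.28 and 1.25. On the axis of 100 other genes the library labelled KO CT10 replicate 3 lay at 0.54. That labelled KO CT22 replicate 1 lay at 0.27, a difference of 0.27. The other KO CT10 libraries lay at 0.39 and 0.42 and the other KO CT22 libraries at 0.57 and 0.53 (pooled SD within a label 0.03), so the labels may have been exchanged. The 100 genes add little weight to this: none passed the threshold between the labels in WT, and the SD rests on 4 libraries. KO CT22 replicate 1 also lay below the KO CT10 libraries rather than among them. A different clock phase in these animals cannot be told apart from an exchange of labels, since both give clock genes near the other label. Such levels were found in both libraries for 6 of the 11 clock genes that separate the labels in WT. The split of the KO libraries that exchanges the pair gave 6 genes and each other split 0, which adds no separate evidence since the pair was picked by its clock genes, and the labels were kept as given.

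Genes lower in KO lay together on chromosome 2. Of 25 tested genes between 175061549 and 178078425, 22 were lower and 10 had an unadjusted p under 0.05, with Gm14420 at 47.5 ± 3.49 CPM in WT and 35.3 ± 3.17 CPM in KO (SD, n = 6 each; edgeR adjusted p = 0.0773). The summed count of the 27 genes there, untested ones included, fell by 0.33 on the log2 scale (log2 change −0.33, SE 0.07). This argues against reads moved between copies inside the cluster. Near Nono, 8 of 87 genes within 10 Mb had an unadjusted p under 0.05 (9.2%), against 888 of 14043 elsewhere (6.32%, Fisher's exact test, two-sided p = 0.266), too few to show or exclude a chromosome segment of another origin kept around the targeted gene. Such a segment on chromosome 2, or copies outside the cluster, could be involved and were not tested. Of the 8 genes near Nono, all but Zdhhc15 were higher in KO. Magt1 among them had a log2 change of 0.41 (edgeR adjusted p = 0.176, DESeq2 adjusted p = 0.0451). It is past 0.05 in the authors' deposited table as well. Magt1 was picked after its value was seen, so it does not settle whether a segment was kept around Nono.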
